A study of Arabidopsis thaliana with 6 samples.

How the data were processed

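Transcript levels were measured in mature rosette leaves of Arabidopsis thaliana, ecotype Col-0, on 6 one-colour Affymetrix ATH1 arrays hybridised with biotin-labelled cRNA. Per the labels, 3 control arrays came from leaves carrying empty aphid cages and 3 aphid arrays from leaves on which 10 caged aphids had been kept for 8 h. The time for which the empty cages stayed on the control leaves is not given in the sources used here. Arrays are named by group and by the number in their title, as control 1, 2 and 3 and aphid 4, 5 and 6. The numbers are not shared between the groups, so the labels pair no arrays, and the tests were run without pairs. Control 3 is titled a repeat; per the labels it had 1453 outlier cells, against 294 to 485 on the other arrays. The labels do not say that the arrays of a group came from separate plantings, so p-values measure the spread between these arrays, part of which may be technical.

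The deposited values were intensity signals on a linear scale, with 1 value per probe set and array. The summarisation and scaling steps are not given in the sources used here. The values showed that each array had been brought to a common level, because the mean after trimming 2% at each end was 100 on all 6 arrays. Genes had not been centred. The median signal was 43.9, 44.2 and 42.7 on control 1, 2 and 3, and 42.2, 43.8 and 41.8 on aphid 4, 5 and 6. No column of another sample was present.

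The table held 22810 probe sets, of which 64 Affymetrix control probe sets were left out of the tests. Signals below 1 were set to 1 and log2 was taken, with no further normalization because the trimmed means were equal. Probe sets whose mean log2 signal lay above the 40th percentile, which corresponded to a signal of 27.5, were tested. This left 13647 of 22746 probe sets. Fits used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with its default prior), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Intervals are 95% intervals of the moderated fit. The number of arrays limits their precision.

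Genes were named from the platform's probe table, with symbols checked by gene number against the RefSeq table of assembly TAIR10.1. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 were unnamed here. Gene number matched 13436 of those with 1 gene, and 0 symbols differed. Unnamed probe sets were tested but are given no gene name, and no coordinates are printed.

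Before the data were examined, 17 gene lists with 241 members were fixed, with a rule for the genes to be named. The rule took all probe sets past the adjusted threshold. Where fewer than 24 passed, it took the 12 higher and 12 lower with the smallest unadjusted p among probe sets of 1 gene whose aphid arrays all lay on the same side of all control arrays. It added the 2 members of each list with the smallest unadjusted p, and 10 fixed genes, of which PDF1.2A alone had a named probe set. By the fixed matching rule a locus counted only if it carried the listed symbol or a synonym. The matching was first run by locus alone and was brought to this rule after those results had been seen. The correction left out UPOX and GC1, whose loci do not carry these names in the annotation, and the closing section gives the results by locus alone.

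Lists with at least 2 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry served as alternatives. Members were also adjusted over the list alone. Array similarity was the Pearson correlation of log2 signals across probe sets, which are not independent replicates, compared within and between groups over the 10 splits of the arrays. RNA integrity was taken as the log2 ratio of the 3' to the 5' signal of the actin, GAPDH and ubiquitin control probe sets, averaged per array. Alternatives were no filter, a filter at the 60th percentile, quantile normalization, centring on the array median, an offset of 13.3 added before log2, a prior with trend and robust estimation, array weights, and leaving out each array in turn. A block by the order of the array numbers, the similarity of arrays at the same place in that order, the count at an unadjusted p under 0.05, and sets of genes sharing a symbol stem or lying on the chloroplast genome were added after the data had been seen.

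The fit was tested on simulated data with 13647 probe sets and independent noise, in 20 draws. With 200 changed probe sets per draw, 67.2% of 2-fold and 97% of 4-fold changes were called, and 4.37% of calls were unchanged probe sets. With 20 changed, 24% of 2-fold and 88.5% of 4-fold changes were called, and 8.16% of calls were unchanged probe sets. In every draw a further 20 probe sets were shifted by less than 2-fold. Calls of these counted among the calls but not as unchanged. The simulated arrays were independent, whereas real arrays at the same place in the number order deviated together, so these rates may not hold for the real arrays.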

Results

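Transcript levels were compared between mature rosette leaves of Arabidopsis thaliana (ecotype Col-0) that carried caged aphids and leaves that carried empty cages. For each sample the labels give 2 mature rosette leaves, growth stage 3.90 and 10 pooled plants. Plants grew in compost at 22 °C and 70% humidity with 18 h days. There were 3 control arrays and 3 aphid arrays, the latter from leaves exposed to 10 caged aphids for 8 h. Both groups carried cages, so caging as such was shared. The comparison addressed the presence of aphids only as far as the cages stayed on equally long, which is not given. The maximum signal ranged from 4250.4 on control 3 to 5700.7 on control 1. The average array background, per the labels, was 87.12, 104.81 and 68.7 on control 1, 2 and 3, and 85.34, 81.45 and 71.61 on aphid 4, 5 and 6.

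No gene passed the test for a difference between aphid and control leaves, and neither did any measured member of the defence, hormone and photosynthesis lists. The named genes below were limited to probe sets of 1 gene whose groups did not overlap. Those higher with aphids were led by AT1G49980, a dim gene with the smallest unadjusted limma p, and by AT3G16530, which encodes a legume lectin-family protein. They also included AT3G26590 and AT1G66760, which encode transporters of the MATE family and had larger unadjusted p of 0.00648 and 0.00654. Those lower with aphids were led by AT4G00090. They also included BUB3.1, a spindle checkpoint protein gene, XTH19, which encodes a cell wall xyloglucan endotransglucosylase/hydrolase, and PRA1.B4, a prenylated RAB acceptor gene, with unadjusted limma p of 0.00124, 0.00353 and 0.00365. Over 13647 probe sets, limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower at the 0.05 threshold, and the smallest adjusted p was 0.986. At an unadjusted p under 0.05, 219 probe sets were higher and 349 lower, 568 in all. With no change and independent arrays 682 would be expected. Of the 10 splits of the arrays, the real one among them, 6 gave a count as large as 568. Arrays at the same place in the number order deviated together. The 3 other splits that part all such pairs gave 261, 305 and 355. The pairing by order was found in these data, and so few splits allow no share under 0.05, so these counts cannot show an excess with aphids. With arrays blocked by the order of their numbers, a pairing that the labels do not give and that was chosen after the data had been seen, the unadjusted count was 1200 and the adjusted count 0 by limma with Benjamini-Hochberg adjustment. The 95% interval of the log2 fold change lay inside a 2-fold change either way for 13024 probe sets, or 95.4%. Its median half-width was 0.36.

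Among the 12 genes named for a higher level, AT1G49980 had the smallest unadjusted limma p, 0.000253. Its signal was 22.2 ± 1.61 (SD, n = 3) in control and 37.7 ± 2.31 (SD, n = 3) in aphid leaves, a log2 fold change of 0.76 ± 0.12 (SE). The control mean lay below the filter signal of 27.5, so its aphid arrays carried it past the filter. With the offset added before log2 its log2 fold change was 0.52. The lectin gene AT3G16530 measured 82.7 ± 13.5 (SD, n = 3) in control and 166 ± 38.5 (SD, n = 3) in aphid leaves, with a log2 fold change of 0.99 ± 0.20 (SE). AT4G27450 was the gene of this group with the second highest signal, at 327 ± 63.4 (SD, n = 3) against 580 ± 77.6 (SD, n = 3) and a log2 fold change of 0.84. The Kelch-repeat F-box gene AT1G23390 had the highest, at 488 ± 65.1 (SD, n = 3) against 756 ± 55.2 (SD, n = 3). AT1G66760 differed most within the group, with a log2 fold change of 1.28 ± 0.35 (SE), but its control arrays spread from 11.7 to 33.9. The log2 fold changes of AT1G55550, AT3G50900, AT3G62950, AT5G66490, AT2G30960, AT3G26590 and AT1G65490 ran from 0.44 to 0.91. The control means of AT1G55550, AT3G26590 and AT1G66760, at 24.4, 23.3 and 22.3, also lay below the filter signal. Each of these 12 genes had an adjusted p of 0.986 with limma and Benjamini-Hochberg adjustment.

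Among the 12 genes named for a lower level, AT4G00090 had the smallest unadjusted limma p, 0.000597, with a log2 fold change of -0.65 ± 0.12 (SE). The PRA1.B4 signal was 152 ± 22.5 (SD, n = 3) in control and 76.9 ± 29.2 (SD, n = 3) in aphid leaves, a log2 fold change of -1.04 ± 0.26 (SE). XTH19 measured 69.8 ± 7.41 (SD, n = 3) against 42.7 ± 8.72 (SD, n = 3), a log2 fold change of -0.73 ± 0.18 (SE). BUB3.1 was dimmer, at 41.7 ± 3.36 (SD, n = 3) against 27.0 ± 2.38 (SD, n = 3), with a log2 fold change of -0.63. AT2G44670 had the highest signal of these genes, 435 ± 28.7 (SD, n = 3) against 289 ± 30.2 (SD, n = 3), and a log2 fold change of -0.59. The log2 fold changes of AT4G15750, AT2G30780, AT2G07776, AT1G35617, AT3G29230, AT5G43310 and AT4G13150 ran from -0.99 to -0.53. The aphid means of BUB3.1, AT2G30780 and AT4G13150, at 27.0, 26.1 and 24.5, lay below the filter signal of 27.5. The adjusted p was 0.986 for each of these 12 as well, with limma and Benjamini-Hochberg adjustment. The 24 genes were picked because their groups did not overlap. Such separation was seen for 1274 probe sets, or 9.34%, and chance gives 10% for 3 arrays against 3 that are exchangeable. Arrays that deviate together across the groups, as those at the same place in the number order did, make separation rarer than that with no change.

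**Figure D1:**
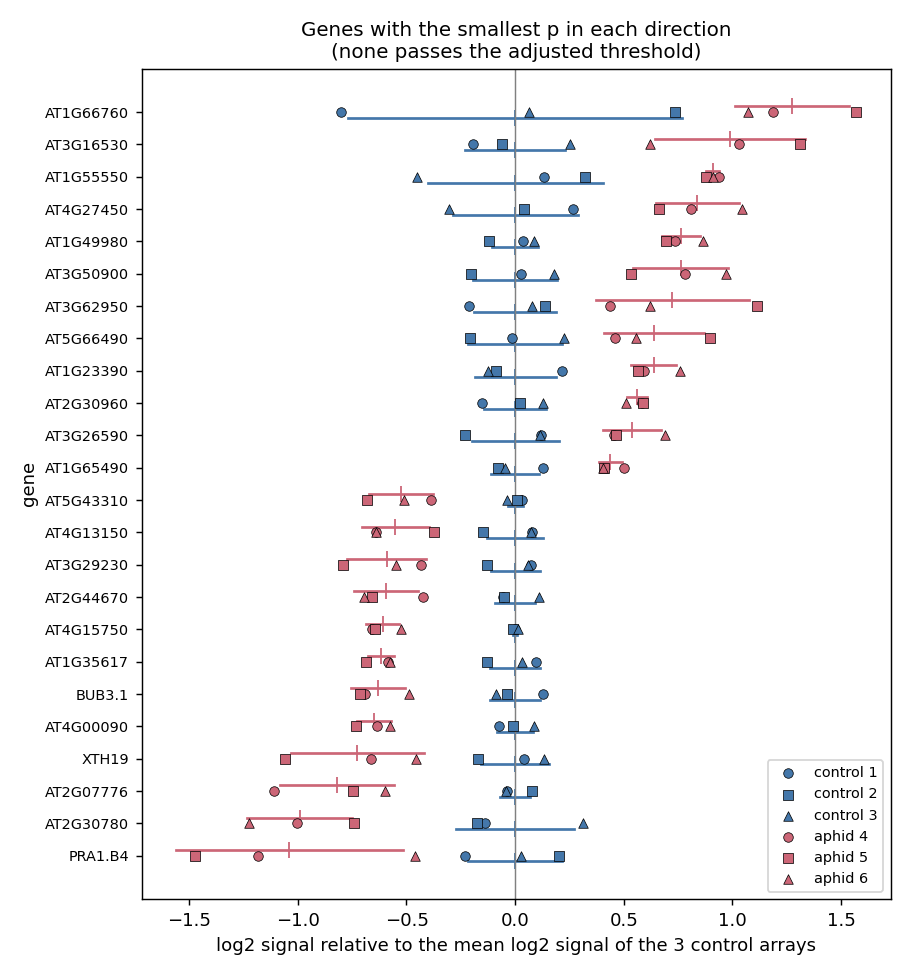
Log2 signal of the 12 higher and 12 lower named genes on each array, relative to the mean of the 3 control arrays. Points are arrays, short vertical ticks are group means and horizontal bars span 1 SD either way; all aphid points lie on the same side of all control points because the genes were chosen that way.

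At an unadjusted p under 0.05 and at least a 2-fold difference, 6 probe sets were higher with aphids and 3 lower. This count was not corrected for multiple tests. Those with 1 named gene were AT1G66760, AT1G20030, AT3G14750 and SIS, which were higher, and PRA1.B4 and AT4G16563, which were lower. The SIS signal was 37.5, 58.2 and 27.7 on the control arrays and 92.1, 110.1 and 55.1 on the aphid arrays, and AT4G16563 measured 136 ± 43.7 (SD, n = 3) against 63.7 ± 23.7 (SD, n = 3). The count of 9 became 42 without control 2, 14 without control 3, 21 without aphid 4, 14 without aphid 5 and 15 without aphid 6. It was 250 with no filter on dim probe sets, 4 with the stricter filter and 2 with an offset added before log2.

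The gene lists asked whether known responses to feeding insects and to wounding, and the leaf's own functions, differed with aphids. A named probe set was found for 26 of the 241 listed members, and 21 of these were bright enough to test, so each list was seen in small part. Of the 21, 14 had a positive and 7 a negative log2 fold change, and 0 passed with limma and Benjamini-Hochberg adjustment over all genes. The count adjusted over the list alone was also 0, as was the count at an unadjusted p under 0.05. Leaving out 1 array turned the direction or moved the log2 fold change by over 1.5 times for each of the 18 members that the naming rule took.

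In the salicylic acid list, GRX480, a glutaredoxin gene of salicylic acid signalling, had the smallest unadjusted limma p of any member, 0.115. Its log2 fold change was 0.36, with a 95% interval from -0.11 to 0.84. SAG101, a lipase-like partner of EDS1 in immunity, had a log2 fold change of 0.02, which became -0.06 without control 2, -0.25 without aphid 6 and -0.0105 with array weights. The early defence list had 4 tested members. The transcription factor genes WRKY22, WRKY53 and ZAT10 had log2 fold changes of 0.23, -0.05 and -0.01, and the calmodulin-like gene CML41 had 0.21, which became -0.20 without aphid 6. For ZAT10 the 95% interval ran from -0.40 to 0.38. In the ethylene list EIN3, the central transcription factor of ethylene signalling, was measured at 463 ± 57.9 (SD, n = 3) in control and 519 ± 56.5 (SD, n = 3) in aphid leaves. Its log2 fold change was 0.17. The jasmonate list had no tested member. The defensin gene PDF1.2A was dim throughout, with signals of 1.1, 0.5 and 13.3 on the control arrays and 12.5, 1.1 and 13.5 on the aphid arrays, and JMT was below the filter as well.

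In the glucosinolate lists, UGT74B1, which adds the sugar in glucosinolate synthesis, had a log2 fold change of 0.23, and BCAT4, an aminotransferase of methionine chain elongation, had 0.30. These ran from 0.08 without control 1 to 0.385 without aphid 4 for UGT74B1, and from 0.10 without aphid 5 to 0.515 without aphid 4 for BCAT4. BCAT4 was bright, at 1110 ± 205 (SD, n = 3) in control and 1390 ± 388 (SD, n = 3) in aphid leaves, and the difference was smaller than the spread between aphid arrays. The cell wall list was divided, with XTH33 at -0.47 and the expansin gene EXPA8 at 0.16. XTH33 ran from -0.75 without control 2 to -0.145 without control 1, and EXPA8 from 0.07 without control 2 to 0.25 without aphid 6. SWEET11, a sucrose exporter that feeds phloem loading, was at 1337 ± 100 (SD, n = 3) in control and 1405 ± 302 (SD, n = 3) in aphid leaves. Its log2 fold change of 0.05 became -0.0051 without control 2, -0.10 without aphid 6 and -0.0041 after quantile normalization. COR15A, a cold- and abscisic acid-induced chloroplast protein gene, varied far more within the groups than between them. It measured 54.8, 631.3 and 80.7 on control 1, 2 and 3 and 60.9, 494.4 and 64.1 on aphid 4, 5 and 6, and its log2 fold change of -0.18 became 0.91 without control 2, 0.34 without aphid 4 and 0.30 without aphid 6.

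None of the 3 tested members of the photosynthesis list passed. RCA, which encodes Rubisco activase, had a log2 fold change of 0.12, the phosphoribulokinase gene PRK 0.10, and the protochlorophyllide oxidoreductase gene PORB 0.01. The 95% interval of PORB ran from -0.32 to 0.34. The clock gene GI had a log2 fold change of -0.05, which became 0.05 without control 3 and 0.07 without aphid 5, and the small heat shock protein gene HSP22.0 had 0.16. In the auxin list IAA29 was at 0.12 and GH3.3 at -0.30. IAA29 turned to -0.06 without control 1, -0.02 without control 3 and -0.21 without aphid 5, and was 0.46 without control 2 and 0.50 without aphid 6. GH3.3 turned to 0.07 without control 2. The guard cell regulator FAMA, a marker of another cell type of the leaf, had a log2 fold change of -0.30, with a 95% interval from -0.72 to 0.11. The senescence list had SAG29 and WRKY6, both below the filter. The oxidative stress and cell division lists had no named probe set.

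**Figure D2:**
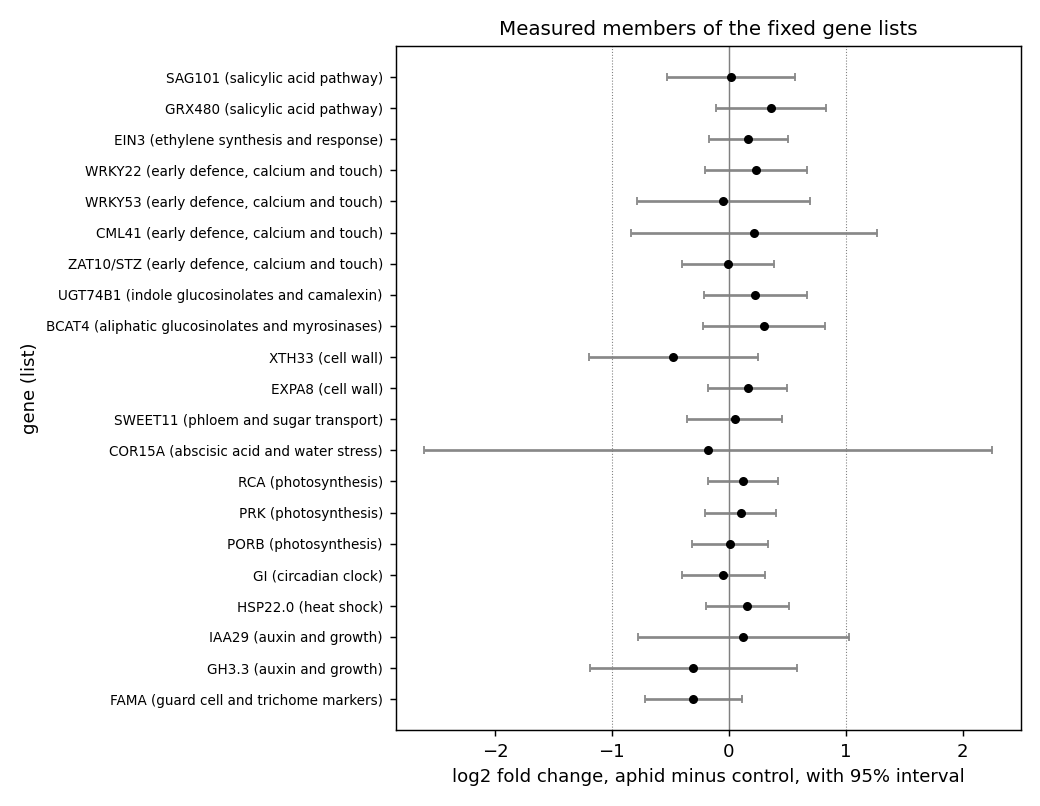
Log2 fold change, aphid minus control, of the 21 tested list members, with points for estimates and bars for 95% intervals of the limma fit; dotted lines mark a 2-fold change. Every interval includes 0, and the widest, that of COR15A, runs from -2.61 to 2.25.

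A set test was possible for 5 lists, and 0 passed. With camera and Benjamini-Hochberg adjustment the adjusted p was 0.648 for the salicylic acid, early defence and photosynthesis lists, and 0.903 for the cell wall and auxin lists. With an estimated correlation the lowest adjusted p was 0.821, and with fry it was 0.924. The other lists had 1 tested member, in 8 cases, or 0, in 4 cases.

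The groups did not separate by overall similarity of the arrays when all pairs were counted. The mean correlation across probe sets was 0.9662 within groups and 0.9681 between them, and the exact one-sided permutation p of the difference was 0.6, where 0.1 is the smallest the design allows. This test took no account of the order of the array numbers. The 3 pairs at the same place in that order, control 1 with aphid 4, control 2 with aphid 5 and control 3 with aphid 6, had a mean correlation of 0.9772, and the other 6 pairs between groups 0.9635, below the mean within groups. This division was chosen after the data had been seen. Of the other 6 pairs, those holding control 2 or aphid 5 ran from 0.9541 to 0.9695. Control 1 with aphid 6 was at 0.9702 and control 3 with aphid 4 at 0.9746, both above the mean within groups. Control 3 with aphid 6, a pair by order, was lower than the latter, at 0.9729. The low mean of the other pairs thus rested on control 2 and aphid 5, and is no separate sign of a pairing by order. The first principal component held 40.5% of the variance and placed control 2 at 21.9 and aphid 5 at 27.7, with the other arrays between -14.7 and -6.83. RNA integrity differed in order between the groups. The mean log2 ratio of 3' to 5' signal was 0.510 ± 0.082 (SD, n = 3) on control and 0.655 ± 0.052 (SD, n = 3) on aphid arrays. In this mean all aphid arrays lay above all control arrays, with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. Of the control transcripts taken alone, only actin separated the groups. For GAPDH aphid 4, at 0.282, lay below control 2, at 0.371. For ubiquitin aphid 6, at 0.74, lay below control 2, at 0.784.

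**Figure D3:**
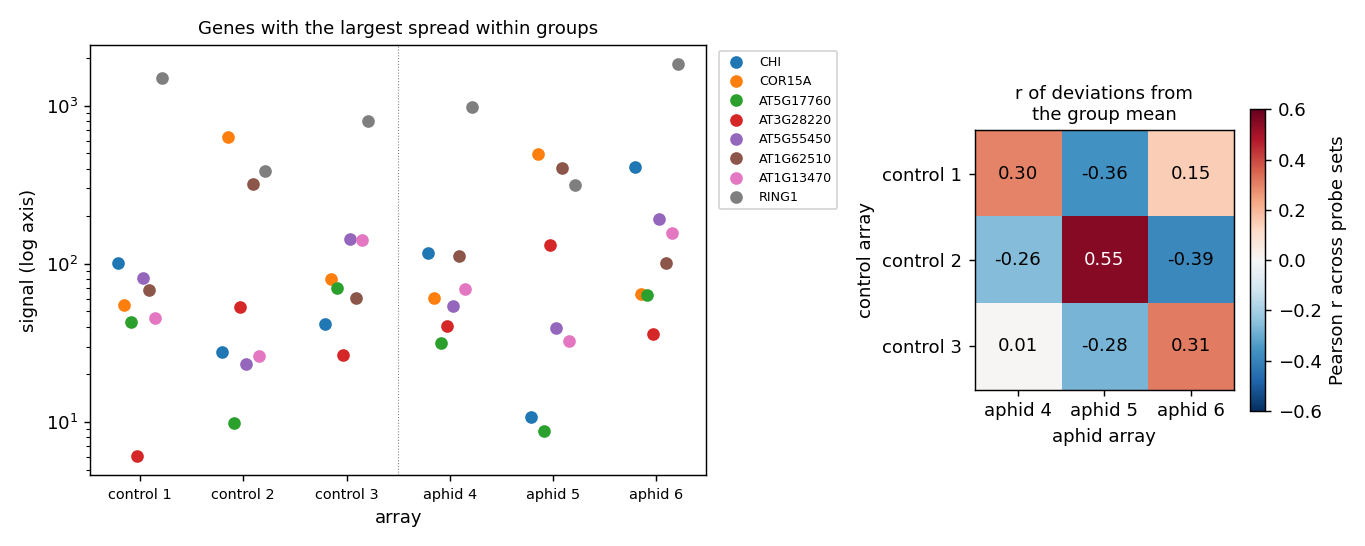
Left, signal on a log axis of the 8 named genes with the largest spread within groups, with 1 point per gene and array. Right, correlation across probe sets of each control array's deviations from its group mean with those of each aphid array, which was 0.546 for control 2 with aphid 5.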

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

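The block by array order, the unadjusted count whatever the fold, the matching by locus alone, and the sets by symbol stem and chloroplast genome with their settings were chosen after the data had been seen; the other alternatives were planned. With limma and Benjamini-Hochberg adjustment, the count of changed probe sets was 0 under every alternative run, with the smallest adjusted p between 0.254 and 1, and it was also 0 at thresholds of 0.10 and 0.20. The unadjusted count of 568 became 1050 of 22746 with no filter, where 1137 would be expected of independent arrays, and 1200 with a replicate block by array order; leaving out 1 array gave 422 to 775. The 2-fold count of 9 became 250 with no filter, 4 with the stricter filter and 2 with the offset, and ran from 6 without control 1 to 42 without control 2. The cause was not tested, except that the filter sets which dim probe sets are counted. No list passed under any alternative, with the lowest adjusted p 0.182, without aphid 4. With members matched by locus alone, 28 members had a probe set, 23 were tested and 6 lists could be tested; 0 passed, and the smallest adjusted p was 0.527. It adds UPOX (log2 fold change 0.10) and GC1 (-0.14). Under the stricter filter 1 list could be tested. The within minus between correlation stayed negative, from -0.0021 to -0.00075. With camera, 3 sets by symbol stem and the chloroplast set passed, 4 in all. The count fell to 0 with an estimated correlation and to 2 with each estimate as the preset correlation. Leaving out 1 array gave 3 to 5. With fry, which tests each set against no change, the count was 0.

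The 24 leading genes were chosen with groups that do not overlap, so leaving out an array cannot turn them. The 18 named list members had 244 values under alternatives, of which 228 kept their direction and 16, of 7 genes, reversed. Leaving out 1 array turned or moved all 18 by over 1.5 times. No named gene became significant (smallest adjusted p 0.441, limma with Benjamini-Hochberg adjustment). SWEET11 was -0.0041 after quantile normalization and SAG101 was -0.0105 with array weights. When arrays were left out, COR15A ranged from -1.17 to 0.91, GH3.3 from -0.661 to 0.0687, IAA29 from -0.21 to 0.50, GI from -0.116 to 0.0707, CML41 from -0.20 to 0.76, SWEET11 from -0.10 to 0.22 and SAG101 from -0.254 to 0.225. The cause was not tested. The filter at a signal of 27.5 left dim genes such as PDF1.2A without a test.

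The arrays make 10 splits of 3 against 3, too few for a share under 0.05. For the adjusted count, the real split gave 0 and the highest other 0, with 10 of 10 splits as large. Every split is as large as a real count of 0, so this comparison and that of the fixed lists below decide nothing. For the unadjusted count the real value was 568 and the highest other 1342, which grouped control 1, control 3 and aphid 4, with 6 of 10 as large. Under the order pairing the matched splits are those that part all 3 pairs, which gave 261, 305 and 355. That pairing was found in these data, and these splits are too few as well for a share under 0.05. For the 2-fold count the real value was 9 and the highest other 100, with 5 of 10 as large. For the fixed lists they were 0 and 1, with 10 of 10. The splits with the largest counts placed control 2 and aphid 5 together, pointing to a structure of the arrays.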

Other observations

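All tests of explanations in this part, and the sets of genes sharing a symbol stem or lying on the chloroplast genome, were chosen after the results had been seen. Of 29 sets that share a stem, with at least 5 tested probe sets each, 3 passed camera with its preset correlation and Benjamini-Hochberg adjustment over these and the chloroplast set, which passed as well. The stem sets of plastid ribosomal proteins hold probe sets that are also in the chloroplast set. The 5 beta-tubulin genes, which encode a subunit of microtubules, all had a negative log2 fold change, with a median of -0.24 and an adjusted p of 0.00306. With an estimated correlation the call was lost (adjusted p 0.467). Fry, which tests the set against no change and not against the other genes, gave an adjusted p of 0.182. TUB1 was at -0.54, TUB7 at -0.39, TUB9 at -0.24, TUB6 at -0.19 and TUB5 at -0.16. Of 8 autophagy genes, ATG3 and members of the ATG8 family, 7 had a positive log2 fold change, with a median of 0.21 and an adjusted p of 0.00488. This call too was lost with an estimated correlation (adjusted p 0.467), and fry gave an adjusted p of 0.182. ATG8F, at 1303 ± 17.8 (SD, n = 3) in control and 1580 ± 30.4 (SD, n = 3) in aphid leaves, had a log2 fold change of 0.28. Its sister ATG8E was at 0.35, ATG8D at 0.0035 and ATG8B at -0.00051, and the last was positive after quantile normalization and after centring. The 13 probe sets with the stem CYP are mostly cytochrome P450 genes of the CYP71B group, but CYP71 itself names a cyclophilin. Of these 13, 12 were positive, with a median of 0.20 and an adjusted p of 0.00556. With an estimated correlation this call was lost as well (adjusted p 0.467), and fry gave an adjusted p of 0.182. No single gene of these sets passed, and the mean log2 ratio of 3' to 5' signal was higher on all aphid arrays than on all control arrays.

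In each of these 3 sets, the real split gave the smallest camera p of the 10 splits. The sets were picked for a small p in the real split, which favours this rank, so it is no separate support. The real split gave 4 passing sets against 2 in the highest other, with 1 of 10 splits as large, and 10 splits are too few for a share under 0.05. The autophagy call was lost without aphid 4 (adjusted p 0.0981). The CYP call was lost without control 1 (median 0.11, adjusted p 0.0682), without aphid 6 (median 0.12, adjusted p 0.0658) and under the stricter filter (0.0535), by camera with Benjamini-Hochberg adjustment. The estimated correlation was 0.232 for beta-tubulin, 0.0707 for autophagy and 0.0181 for CYP, and the test that estimates it has 4 degrees of freedom in place of 13645, so the loss at an adjusted p of 0.467 is not due to correlation alone. With each estimate given as the preset value, the adjusted p was 0.0636 for beta-tubulin, 0.0476 for autophagy and 0.0363 for CYP. Whether correlation between genes may account for these calls stays open, since the estimates from 6 arrays come with no error. RNA integrity stays open too, because the lowest aphid array exceeded the highest control array by 0.009 on the log2 scale of the mean 3' to 5' ratio. Between the groups this mean cannot be told apart from aphid exposure, because it runs with them. The GAPDH and ubiquitin ratios taken alone overlapped between the groups. The ratio also varied within the groups, but whether the sets followed it there was not tested.

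Transcripts of the chloroplast genome were defined as a set by their genome, not by a stem. Of 69 probe sets, 56 had a positive log2 fold change, with a median of 0.10 and an adjusted p of 0.00172 by camera at its preset correlation. The adjusted p was 0.622 with an estimated correlation, which was 0.348 between these genes, and 0.517 with that estimate given as the preset value, and 5 of the 10 splits gave a p as small. The median was 0.0013 and the adjusted p 0.93 without control 2, 0.07 and 0.067 without aphid 5, and 0.04 and 0.195 after quantile normalization. The call held when another array was left out, with a median of 0.17 and an adjusted p of 5.04e-08 without control 1, and adjusted p of 8.11e-05 without control 3, 0.000411 without aphid 4 and 0.0052 without aphid 6. These values are consistent with correlated transcripts that vary between arrays as a block. An effect of aphid exposure was not tested apart from this.

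Control 2 and aphid 5 resembled each other across the group boundary. Among the 200 probe sets with the largest spread within groups, these arrays were together at the same extreme in 150, and the next pair, control 3 and aphid 6, in 56. Choosing probe sets by their spread within groups favours pairs that cross the groups, so these counts have no chance value here. COR15A was high on both, and the chitinase gene CHI was low on both, at 101.6, 27.6 and 41.5 on the control arrays and 116.8, 10.8 and 407.9 on the aphid arrays. RING1 followed CHI, at 1500.1, 388.1 and 799.4, then 985.1, 314.3 and 1832.2, and AT1G62510 followed COR15A, at 68.6, 319.2 and 60.4, then 111.9, 403.8 and 100.8. These genes were named after their values were seen.

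Array background as a shared property of control 2 and aphid 5 is argued against, because the background of aphid 5 lay below the highest of the other aphid arrays (difference -3.89, SD over the array 2.06). RNA integrity stays open: the log2 ratio of 3' to 5' signal of control 2 differed from the mean of aphid 4 and aphid 6 by -0.027, less than the SD of 0.092 over 3 control transcripts. Within its own group each had the highest ratio, 0.6 on control 2 against 0.491 and 0.439, and 0.712 on aphid 5 against 0.609 and 0.643. A candidate explanation is that arrays at the same place in the number order were grown or handled together. Deviations from the group mean correlated across probe sets at 0.299 for control 1 with aphid 4, 0.546 for control 2 with aphid 5 and 0.311 for control 3 with aphid 6, the highest mean of the 6 possible matchings. That mean was 0.385. The next highest, 0.233, matched control 1 with aphid 6 and control 3 with aphid 4, and also held control 2 with aphid 5. Deviations within a group cancel, so a resemblance of control 2 and aphid 5 alone pushes the remaining arrays of both groups the same way. That the other 2 pairs by order correlated positively is thus not separate support. The push does not by itself account for their lying above control 1 with aphid 6, at 0.146, and control 3 with aphid 4, at 0.00785. The labels give no pairing by order, and it was found in these data, so it remains a hypothesis. With the pairing as a block, limma with Benjamini-Hochberg adjustment called 0 probe sets. An unadjusted limma p under 0.05 was found for 1200, against 472 to 613 in the other splits that part all 3 pairs. The pairing was chosen from deviations within the real groups, which lowers the residual spread of the real split and favours it here. These splits are also too few for a share under 0.05. No biological explanation for the resemblance was tested.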
